A study of Caenorhabditis elegans with 2 samples.

How the data were processed

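Poly(A) tail lengths were measured by mTAIL-seq in whole wild-type C. elegans of the N2 Bristol strain at the last larval stage, L4. Per the labels' protocols, animals synchronized by standard methods were grown at 25 °C on OP50 bacteria and collected at 29 h, and Trizol-extracted, DNase-treated RNA was used. In mTAIL-seq a splint oligonucleotide favours ligation of the 3′ adapter to RNAs that end in poly(A). Per the labels' protocols, the ligated RNA was partially digested with RNase T1, pulled down on streptavidin beads, 5′ phosphorylated and size-selected for fragments of 250 to 1000 nt. Sequencing was on an Illumina MiSeq with 51 cycles for read 1 and 251 cycles for read 2, together with PhiX and spike-in controls. Tail lengths were called by the authors with tailseeker2 from the fluorescence signals, per the labels. Per the submitters' processing notes, STAR and bedtools were also used; their roles, versions and the genome build and annotation are not given in the sources used here.

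The labels describe 2 biological replicates of 1 group. The deposited table has 1 row per gene and does not tell the replicates apart, so all values are pooled over both libraries and carry no replicate error. The deposited counts are the number of tail calls (tags) per gene and are not normalized. The table also gives each gene's list of tail lengths in nt, with the mean, median, SD, maximum, minimum and range of that list. Recomputing the count, mean, median and SD from the list gave 0 differing genes out of 13601; the SD in the table is the population SD. Every listed gene had at least 10 tags. Whether tags were collapsed to distinct molecules is not given in the sources used here.

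From these lists each gene was turned into a histogram of tail lengths. The main analysis used the 8803 genes with at least 100 tags, which hold 98.8% of tags. The design fixed before the data were examined asked for 50 tags in each of 2 replicates, taken here as 100 over the pooled table once the pooling was seen. The main value per gene was its median tail length. Its 95% interval came from 500 bootstrap draws of the gene's own tags, so it covers counting error only, and PCR copies, if present, would make it too narrow. Genes were called short or long when their median lay at least 20 nt below or above the median over genes and the interval lay on the same side; this size was chosen after the table was read. Abundance was expressed as tags per 1000000 listed tags, on a log2 scale for Pearson's r. Correlations are across genes, which are not independent replicates, and no p-value is given for them; their intervals come from 1000 bootstrap draws over genes, and those of medians over genes from 2000 draws.

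Before the data were examined, 29 gene lists were fixed as patterns on gene symbols. They covered ribosomal proteins, mitochondrial ribosomal proteins, translation factors, nuclear-encoded respiratory chain subunits, the mitochondrial genome, glycolysis, the proteasome, chaperones, the vacuolar ATPase, splicing factors, cuticle collagens, molting genes, muscle, intestine, vitellogenins, sperm, germline and maternal regulators, histones, neuropeptides, antimicrobial peptides, C-type lectins, neuronal genes, transcription factors, chemoreceptors, signalling kinases, heterochronic genes, poly(A) and decay factors, detoxification enzymes, and F-box, MATH and BTB genes. The 27 lists with at least 5 genes analysed were compared with 10000 random lists of the same size drawn from the other genes, either freely or matched on tag number in 20 bins, and each list's percentile describes these pooled libraries only. Symbols came from the table itself (6653 genes) or, where it gave a protein identifier, from NCBI's table for the WBcel235 assembly, matched on sequence name; 13549 genes matched. That assembly may differ from the one the authors used, so no coordinates are given. Genes named in the text were chosen by a rule also fixed beforehand: the 10 shortest and 10 longest medians with an interval clear of the median over genes, the 10 genes with the most tags, and in each list the 2 most abundant, the shortest and the longest member. The exception, 1 gene that shares a protein identifier, is marked where it occurs.

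For the periodicity of tail lengths, the histogram from 10 to 200 nt was divided by its 41 nt running mean, and the autocorrelation was computed at lags of 15 to 60 nt, with 200 bootstrap draws over genes. Local maxima of the histogram were read from its 5 nt running mean. The division, the smoothing and the scan of gene families by symbol were chosen after the table was read. On simulated data for 2000 genes, 98% of genes shifted down by 25 nt and 100% of genes shifted up were called, 0% of unshifted genes were called, and 97% of the tag bootstrap intervals held the true median. Apart from the shift, all simulated genes drew independent tags from the same distribution, without its shortest and longest tails. These rates therefore do not cover PCR copies, differences between replicates or the pile-up at the longest call. A simulated list shifted by 10 nt lay at percentile 0 and an unshifted one at 57.2. Most simulated genes shared the same true median, whereas the measured gene medians had an interquartile range of 22 nt. The simulated lists therefore do not measure how well a shifted list would stand out among the measured genes. Simulated periods of 22, 27 and 34 nt were recovered exactly. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

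Alternatives varied the minimum number of tags, the summary per gene, the range of tail lengths, the weighting, the running mean, the centring value and the genes included. Because the table pools the replicates, the planned test of each gene across replicates with limma, the planned rank-sum test in each replicate, the agreement between replicates and the leaving out of each replicate could not be made. Transcript architecture and additions at the 3′ end of the tail were not analysed here, for want of a genome and of such columns in the table.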

Results

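Poly(A) tail length was profiled in wild-type L4 C. elegans to describe tail lengths across the transcriptome of 1 developmental stage. The pooled table of 2 biological replicates held 17376490 tags, each a tail length called between 5 and 231 nt, in 13601 genes. Genes ranged from 10 tags, the lowest number listed, to 322583 tags, with a median of 193 tags. The 100 most abundant genes held 43.7% of all tags. Depth per replicate is unknown, because the table does not tell the replicates apart. All comparisons below are therefore between genes or gene groups within this pool, with no replicate check and no test; intervals cover counting error only, unless they are said to be bootstraps over genes.

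Across all tags the median tail was 58 nt and the middle 50% of tags lay between 37 and 86 nt. Tails under 30 nt made up 9.33% of tags (95% Wilson interval 9.32 to 9.34%) and tails over 100 nt made up 16.2% (16.2 to 16.2%). Ribosomal protein genes, which encode the protein components of the cytosolic ribosome, held 32.7% of tags and had a median of 43 nt over their tags, with 3.31% of tails over 100 nt. Tags of all other genes had a median of 68 nt, with 22.5% of tails over 100 nt. With each of the 8803 analysed genes counted once, the median of the gene medians was 80 nt (95% bootstrap over genes 80 to 80.5 nt) and the middle 50% of genes lay between 69 and 91 nt. The longest callable value, 231 nt, held 0.306% of tags, more than its neighbouring lengths, so those values are read as lower bounds.

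**Figure D1:**
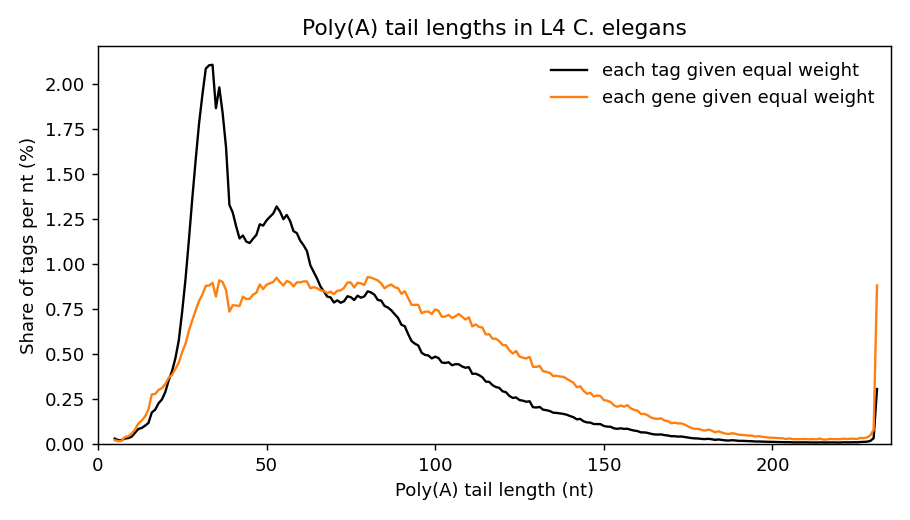
Share of tags (%, y axis) at each poly(A) tail length (nt, x axis), with each tag (black) or each gene with at least 100 tags (orange) given equal weight. Tags peak at 34, 54 and 80 nt, the gene-weighted curve is flatter between 35 and 82 nt, and both pile up at 231 nt.

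The tail length distribution had more than 1 maximum. Smoothed over 5 nt, the first 3 maxima of the tags lay at 34, 54 and 80 nt, with troughs at 44 and 71 nt. The count per nt at the maximum at 54 nt was 1.13 times that of the trough before it, and at 80 nt it was 1.04 times. The maxima lay at the same lengths in ribosomal protein genes alone and in all other genes together, and at 35, 54 and 82 nt when each gene was given equal weight. Just past the first maximum the unsmoothed tags dipped at 35 and 39 nt, to 0.913 and 0.905 times the mean of the neighbouring lengths. Whether such features come from the length calls was not tested. A feature of the calls would recur in every gene set, so the shared lengths cannot decide this. The autocorrelation of the detrended distribution was highest at a lag of 53 nt, in 200 of 200 bootstrap draws over genes, with a lower local maximum at 29 nt. With a 31 nt in place of a 41 nt running mean for the detrending, the highest lag was 28 nt. These autocorrelations were 0.13 at 53 nt and 0.095 at 29 nt. A simulated distribution with no period gave 0.01 and one with a regular 27 nt period gave 0.84. The simulated counts fell from the shortest tails on, whereas the measured counts first rose to the maximum at 34 nt. The simulated values therefore do not measure how periodic the measured tails were.

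Genes differed widely in median tail length, from 29 to 162 nt. Of the 8803 genes, 1039 (11.8%) were short, with medians at least 20 nt below the median over genes and intervals clear of it, and 1107 (12.6%) were long by the same measure. Centred on the median over tags, 58 nt, instead, 42 genes were short and 4953 long. With the mean of log2(tail length + 1) per gene 498 were short and 650 long, with a minimum of 400 tags 447 and 466, and with all listed genes 1736 and 1805. The shortest medians were those of F23A7.4, at 29 nt (95% interval 28 to 30 nt), and irld-23 (C30G4.6), at 30 nt (27 to 31 nt). They were followed by nssp-68 (F53F4.17) and ins-24 (ZC334.3), an insulin-like peptide gene, both at 31 nt, by Y40C7B.4 and C08E3.1, both at 31.5 nt, by R102.2 at 32 nt, and by Y39G8B.9, Y48E1B.8 and nlp-80 (T04C12.3), all at 34 nt. The 3 most abundant of these 10, Y39G8B.9, R102.2 and Y48E1B.8, had 4421, 3026 and 1919 tags. C08E3.1 shares its protein identifier with C08E3.13, a gene named here after its values were seen, which had a median of 56 nt, so the values of this pair are uncertain.

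The longest medians were those of del-5 (F59F3.4), a gene of the degenerin-like ion channel family, at 162 nt (151 to 175 nt), svh-1 (C07G1.1) at 157.5 nt (138 to 182 nt), D2096.10 at 154 nt, glr-6 (F41B4.4), a glutamate receptor gene, at 150 nt, and F38A1.9 at 149.5 nt. The next 5 were sgca-1 (H22K11.4) at 148.5 nt, wshc-5 (T05E7.3) at 146 nt, F59C12.4 at 142.5 nt, math-3 (C08F1.4) at 142 nt and F59E12.15 at 141 nt. These 10 genes had between 100 and 623 tags, and in all 10 over 70% of tails exceeded 100 nt. Short genes as a class had a median of 738 tags and long genes a median of 241 tags.

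The 10 genes with the most tags all had medians of 50 nt or less. They were 2 cuticle collagen genes, col-144 (B0222.6) and col-117 (T28C6.4), both at 49 nt, the translation elongation factor gene eef-1A.1 (F31E3.5) at 50 nt, and 7 ribosomal protein genes between 36 nt (rpl-10) and 47 nt (rps-25). rpl-18 and rpl-43 had medians of 42 and 41 nt, rpl-1 also of 41 nt, and rpl-26 and rla-1 of 45 nt. The interval of each of these medians was at most 1 nt wide, because each rested on at least 136727 tags.

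Median tail length was lower in genes with more tags. Spearman's rho across the 8803 genes was -0.30 (95% bootstrap over genes -0.32 to -0.28) and Pearson's r with log2 abundance was -0.35; both are correlations across genes, which are not independent replicates. The slope was -3.34 nt per doubling of tags. Among 10 equal groups of genes ordered by tags, in the group with the fewest tags, with a median of 116 tags, the median of the gene medians was 86 nt (bootstrap 84.5 to 88 nt). It was 82 nt in the fifth and the sixth of the 10 groups, 75 nt in the ninth and 67 nt (66 to 69 nt) in the group with the most tags, whose median was 5099 tags. Without ribosomal protein genes rho was -0.28. Each gene's abundance was read from the same tags as its tail length, so no independent measure of abundance enters this relation.

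**Figure D2:**
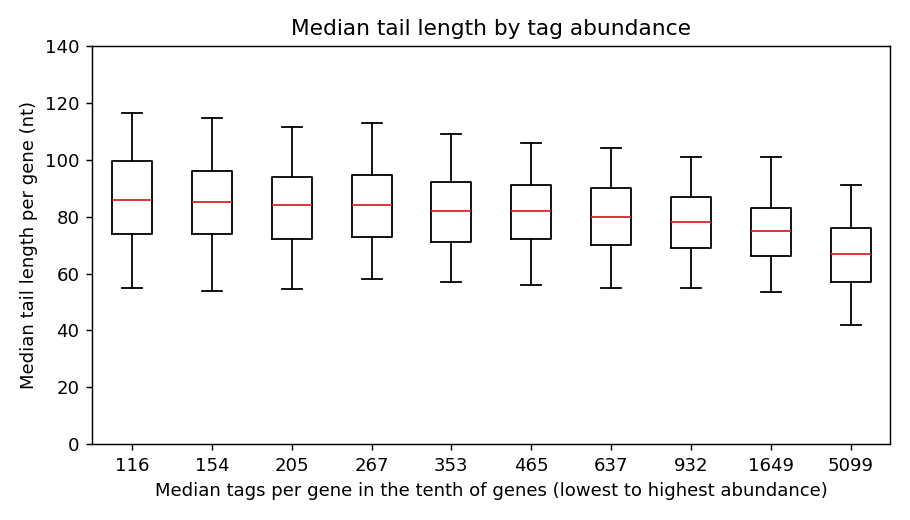
Median tail length per gene (nt, y axis) in 10 groups of genes ordered by tag number, labelled on the x axis with the median tags of the group. Boxes span the middle 50% of genes, red lines are medians and whiskers run from the 5th to the 95th percentile; the median declines from 86 nt at the left to 67 nt at the right.

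Ribosomal protein genes had the shortest tails of the 27 fixed lists. The median of their 81 gene medians was 42 nt (bootstrap over genes 41 to 43 nt), and all 81 had intervals below the median over genes. Here and in the lists and families that follow, genes counted as below or above had intervals wholly on that side. Members ranged from rpl-10 (F10B5.1) at 36 nt to rla-0 (F25H2.10), which encodes ribosomal stalk protein P0, at 59 nt. The list median lay below that of all 10000 random lists, both unmatched and matched on tags. Matching was incomplete here, since the matched lists had a median of 9219 tags per gene and the ribosomal protein genes 66108 tags. Proteins of the mitochondrial ribosome had a median of 71 nt, at percentile 0.025 of matched lists, with 44 of 68 genes below, 10 above and 14 with intervals that included the median over genes. Their 2 most abundant members, mrpl-17 and mrps-16, had medians of 64 and 56 nt, and mrpl-14 and mrpl-24 marked the range at 49 and 96 nt.

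Other housekeeping lists had medians between 65 and 75 nt and, apart from the proteasome, lay within the middle 95% of abundance-matched lists. Proteasome subunits had a median of 65 nt, at percentile 0.31 of matched lists, and 32 of 33 had intervals below the median over genes. Members ranged from rpn-7 at 57 nt to rpn-1 at 78 nt, whose interval included that median. Nuclear-encoded respiratory chain genes had a median of 67 nt, with 39 of 47 genes below, including the cytochrome c gene cyc-2.1 at 51 nt and the adenine nucleotide translocator gene ant-1.1 at 56 nt. Translation factors (median 72 nt, 31 of 40 below) ranged from iff-1, a translation factor 5A gene, at 38 nt to eif-2A at 91 nt. Chaperones (72.3 nt, 34 of 52 below; percentile 4.76, but 1.12 with mean tails and 1.72 with tails of at least 20 nt) included the Hsp90 gene daf-21 at 48 nt and the Hsc70 gene hsp-1 at 57 nt. Glycolytic enzymes (71.5 nt, 14 of 18 below), splicing factors (72 nt, 21 of 32 below) and vacuolar ATPase subunits (75 nt, 15 of 20 below) lay at percentiles 24.3, 13.2 and 92.9 of matched lists. In these lists gpd-3, a glyceraldehyde-3-phosphate dehydrogenase gene, had a median of 58 nt, the Sm protein gene snr-7 of 54 nt and vha-10 of 65 nt.

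Cuticle collagens had a median of 67 nt, at percentile 0.025 of matched lists, with 70 of 96 genes below the median over genes and 16 above, from col-180 at 39 nt to col-47 at 119.5 nt. Molting and other apical matrix genes had a median of 86 nt, at percentile 98.5 (94.6 with mean tails), with 35 of 64 genes above and 15 below, from cut-2 at 57 nt to ptr-14 at 120 nt. Muscle genes had a median of 75 nt, below the median over genes but at percentile 98.4 of matched lists, whose median was 70 nt. That percentile was 97.1 with mean tails, 97.2 with a minimum of 20 tags and 96.4 with all listed genes, outside the highest 2.5%. Of 41 muscle genes 27 lay below and 9 above, among them the troponin C gene pat-10 at 75 nt, the myosin light chain gene mlc-3 at 72 nt, the actin gene act-1 at 52 nt and the twitchin gene unc-22 at 113 nt. Intestinal genes (69 nt, 34 of 47 below) lay at percentile 27.4 and ranged from the aspartyl protease gene asp-1 at 50 nt to the ferritin gene ftn-1 at 113 nt. Collagen and actin genes have near-identical relatives, so the division of tags among them is uncertain.

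Sperm genes and histones had short tails at modest tag numbers. Sperm genes, which include the major sperm protein genes, had a median of 56 nt (bootstrap 53.5 to 57 nt), with 41 of 48 below the median over genes and 6 above, against 82 nt in matched lists, and lay below all 10000 of those lists. Taken as separate medians over these genes, the share of tails under 30 nt was 3.93% and the share over 100 nt was 3.53%. Not all members were alike, since the spe genes (9 genes) had a median of 92 nt, with 6 above the median over genes and 2 below. msp-40 had a median of 59 nt, nspd-4 of 58 nt and msp-64 of 41 nt, and spe-15, a myosin gene, was the longest at 113.5 nt. Histone genes had a median of 64 nt, with 29 of 33 below, and also lay below all matched lists; the 2 most abundant, his-37 and his-72 (the latter encoding a variant H3.3 histone), were at 75 and 76 nt, and his-48 and hil-2 marked the range at 50 and 97 nt. Many major sperm protein and histone genes are near-identical in sequence, so their individual values are uncertain. Because mTAIL-seq favours RNAs that end in poly(A), the tags of histone genes need not represent all of their RNA. Germline and maternal regulators had a median of 73 nt, at percentile 0.445 (2.86 with means of log2 tails and 14.9 with a minimum of 400 tags), with 23 of 43 below and 11 above, from cbd-1 at 36 nt to the meiotic axis gene him-3 at 122 nt. Their most abundant members, the Y-box gene cey-1 and the Vasa-related helicase gene glh-1, were at 60 and 74 nt. Of the vitellogenin genes, which encode yolk proteins, 3 were listed and 2 had at least 100 tags, too few for a list comparison, and the list of the mitochondrial genome had 0 genes analysed.

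Neuropeptides and C-type lectins had short tails although their genes held few tags. Neuropeptide genes had a median of 59.5 nt (bootstrap 57 to 62 nt) at a median of 324 tags, with 68 of 81 below the median over genes and 4 above, and lay below all 10000 matched lists, whose median was 82 nt. The most abundant, nlp-40 and nlp-36, had medians of 71 and 57 nt, and the range ran from ins-24 at 31 nt to ins-33 at 94 nt. C-type lectin genes had a median of 64 nt, with 32 of 45 below, and also lay below all matched lists, with clec-85 at 37 nt, clec-63 at 54 nt and clec-187 at 98.5 nt. Neuronal genes other than peptides had a median of 80.5 nt, at percentile 46.1, with 8 of 26 below and 8 above. Within that list the neuropeptide-processing genes egl-21, a carboxypeptidase gene, and egl-3, a proprotein convertase gene, had medians of 40 and 56 nt, and the synaptic gene unc-13 of 110.5 nt. Detoxification genes (75 nt, percentile 0.075) had 42 of 89 members below and 22 above, from gst-38 at 37 nt to ugt-55 at 111 nt. Their families differed. The gst genes (19 genes) had a median of 65 nt at percentile 0.19, with 15 below and 0 above. The ugt genes (38 genes) had a median of 78 nt at percentile 6.1. The cyp genes (29 genes) had a median of 84 nt at percentile 58.6, with 10 below and 12 above. Antimicrobial peptide genes had a median of 72.5 nt, at percentile 32.8, with 20 of 39 below and 15 above, from spp-3 at 42 nt to cnc-10 at 108 nt.

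Transcription factors, signalling kinases and the heterochronic list had long tails as whole lists. The patterns of these lists overlap, and let-60 is in both the kinase and the heterochronic list. The heterochronic pattern also names a kin gene of the kinase pattern and several genes of the transcription factor pattern. The results of these lists are therefore not separate. Transcription factors had a median of 98 nt (bootstrap 94.5 to 100 nt), above that of all 10000 matched lists, with 106 of 147 genes above the median over genes and 6 below. The most abundant, atf-5 and the hypoxia factor gene hif-1, had medians of 77 and 90 nt, and ceh-62 and zip-12 marked the range at 58 and 134 nt. Signalling kinases had a median of 88.3 nt, at percentile 99.9, with 33 of 60 above and 8 below, from kin-24 at 53 nt to the p38 kinase gene pmk-2, with a 95% interval of 113 to 133 nt. Within this list the kin genes (15 genes, 81 nt, percentile 55.2) and the cdk genes (8 genes, 77 nt, percentile 26.4) were not long as families. Families of fewer than 8 genes were not scanned. The heterochronic list, fixed around genes that time larval development, had a median of 93 nt, at percentile 99.3. Of its 17 genes, 11 had intervals above the median over genes and 0 below it. The list ranged from ain-2 at 76 nt, with an interval that included that median, to hbl-1 at 121 nt. Its 2 most abundant members are better known for other functions, the chromatin remodelling gene let-526, at 90 nt, and the Ras gene let-60, at 82 nt with an interval of 79 to 85 nt that included the median over genes. Genes for poly(A)-binding, deadenylation and decay factors had a median of 82.3 nt, at percentile 79, with pab-1, the cytoplasmic poly(A)-binding protein gene, at 63 nt, lsm-7 at 48 nt and smg-1, a nonsense-mediated decay kinase gene, at 110 nt. F-box, MATH and BTB genes had a median of 85.3 nt, at percentile 70.6 (99.6 with a minimum of 20 tags and 100 with all listed genes), with 34 of 72 above and 19 below and a range from bath-36 at 36 nt to math-3 at 142 nt. Only 7 chemoreceptor genes had enough tags; their median was 79 nt, at percentile 30.5.

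**Figure D3:**
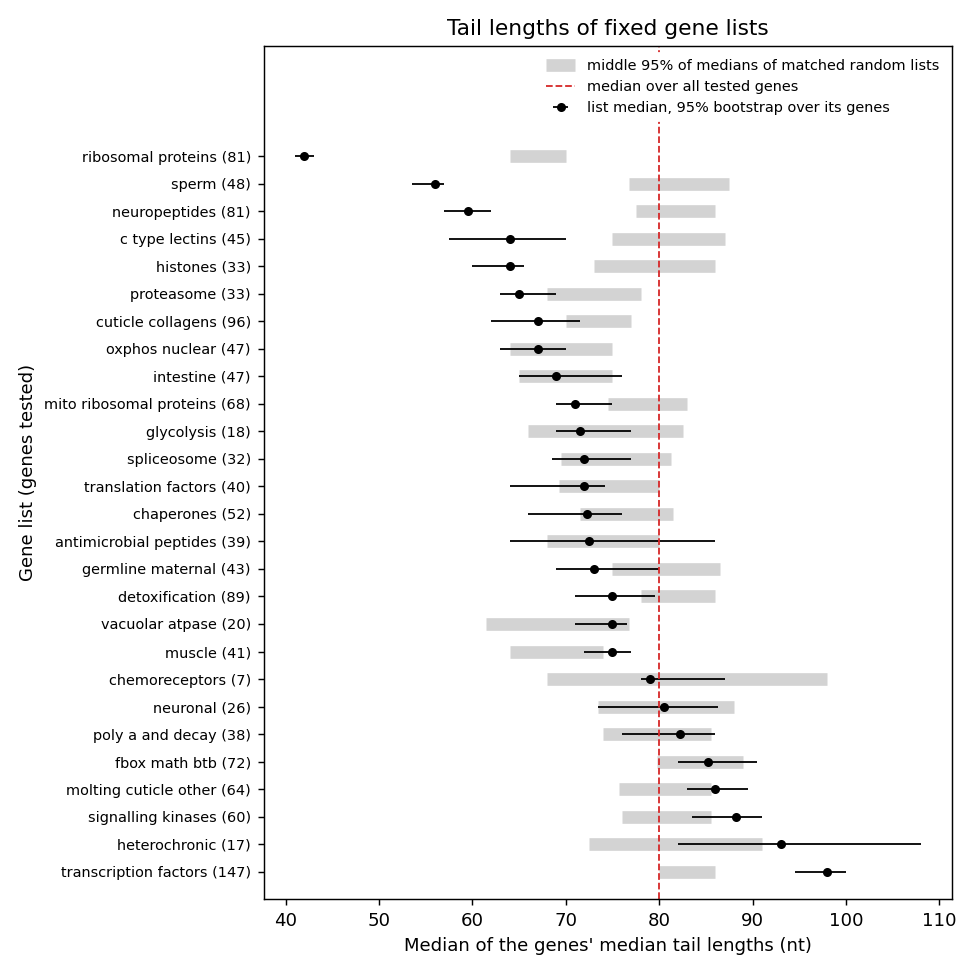
Median of the gene medians (nt, x axis) of each of 27 gene lists (y axis, number of genes in parentheses); points are list medians with 95% bootstrap intervals over the list's genes, grey bars are the middle 95% of medians of random lists matched on tags, and the dashed line is the median over all analysed genes, 80 nt. Of the lists, 10 lie to the left of their grey bars, among them ribosomal protein, sperm, neuropeptide, C-type lectin and histone genes, and 5 to the right, among them transcription factors.

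Of the 27 lists, 10 lay at or under the 2.5th percentile of matched lists and 5 in the highest 2.5%, where chance would put 0.675 at each end. With mean tails 3 lists lay in the highest 2.5%, without the muscle and molting lists. Against random lists not matched on tags the numbers were 16 and 5. The number by chance takes the genes of a list as independent. Some lists hold near-identical genes among which the division of tags is uncertain, and some lists share genes. That number is therefore only a rough guide.

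Tails of a single gene varied more than medians did between genes. The median interquartile range of tail length within a gene was 54 nt, against 22 nt for the interquartile range of the gene medians. The spread within a gene also holds the error of single calls and any difference between the pooled replicates. These parts could not be told apart, whereas each gene median rested on at least 100 tags. The spread within genes was lower in abundant genes, with a median interquartile range of 58 nt in the group of genes with the fewest tags and 44 nt in the group with the most. The share of tails over 100 nt was 38.0% and 18.1% in these groups, and the share under 30 nt was 5.79% and 7.53%. Across genes Spearman's rho of the interquartile range was -0.31 with abundance and 0.49 with the median tail, which was itself lower in abundant genes. Short genes still carried long tails, with 12.1% of tags over 100 nt in the median short gene, and in the median long gene 4% of tails were under 30 nt.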

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

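The minimum of 10 tags and the thinning of genes to 100 tags were chosen after seeing the data; the other alternatives were fixed beforehand. The planned minimums of 10 and 200 tags per replicate were taken as 20 and 400 over the pooled table. Lists were not centred on the median over tags. Under the alternatives run for lists 1 list changed side of the median over genes, the chemoreceptors. It moved from -1 nt to 3.5 nt with a minimum of 20 tags, 5.5 nt with 10 tags, 0.38 nt with means and 2.82 nt with log2 means. Taken as distances from each setting's own centre, 168 of 188 list values stayed within the list's bootstrap interval. Of 967 such values of named genes only 429 stayed within the gene's interval. A gene's own median does not change with the minimum number of tags, so in those settings only the centre moved. Means per gene were set against intervals of medians. With all 13601 listed genes (10 or more tags) the median over genes was 82 nt, short and long genes numbered 1736 and 1805, rho was -0.24 and Pearson's r -0.28. With a minimum of 20 tags they were 81.5 nt, rho -0.25 and r -0.29, and with 400 tags 76 nt, 447 short and 466 long genes, rho -0.32, r -0.39 and a median spread within genes of 51 nt; fewer genes enter at the higher minimum. Tails of at least 20 nt gave a median over genes of 81 nt, and leaving out tails of 227 to 231 nt gave 79.5 nt and a median over tags of 57 nt; the spread within genes was 53 nt in both. Giving each gene equal weight raised the median tail to 79 nt. Mean tails per gene gave rho of -0.33, r of -0.38 and 3 lists in place of 5 in the highest 2.5% of matched lists, and means of log2(tail length + 1) gave 498 short and 650 long genes; the cause was not tested. Without ribosomal protein genes r was -0.30. The lag of the highest autocorrelation, 53 nt, became 52 nt with a 61 nt running mean and 28 nt with a 31 nt running mean, so which of its 2 maxima is the higher depends on the detrending. Centred on the median over tags, 58 nt, instead of the median over genes, 42 genes were short and 4953 long, which follows from the lower centre. By the same construction these genes moved from below to above the centre: rla-0 (1 nt), mrpl-17 (6 nt), aldo-2 (11 nt), pbs-6 (5 nt), pas-3 (4 nt), vha-10 (7 nt), vha-2 (9 nt), vha-6 (1 nt), snr-2 (10 nt), pat-10 (17 nt), mlc-3 (14 nt), msp-40 (1 nt), cey-1 (2 nt), glh-1 (16 nt), his-37 (17 nt), his-72 (18 nt), nlp-40 (13 nt), nlp-24 (9 nt), snb-1 (11 nt), atf-5 (19 nt), kin-19 (13 nt), kin-3 (16 nt), pab-1 (5 nt), gst-5 (7 nt) and bath-42 (14 nt). For rpn-1 (20 nt) and ain-2 (18 nt), whose intervals included the median over genes, the same held. In addition, rpn-1 lay 2 nt and atf-5 lay 1 nt above the median over genes with a minimum of 400 tags, wrt-10 moved from 1 nt above to -0.5 nt with 20 tags and -1 nt with 10 tags, and the mean tail of ntl-2 lay -0.18 nt from the median of the gene means. No paired analysis was possible because the table pools both replicates of 1 group, and for the same reason no replicate could be left out, and neither the limma test without a trend nor the rank-sum test was run. No entry of the table names more than 1 gene and no clone number is given, so those alternatives were not run, and non-coding genes were not told apart; leaving out histones gave rho of -0.30. Depth limits single genes: the interval of a median was 17.6 nt wide in the median gene with 100 or more but under 200 tags, 1 nt wide in genes with at least 5000 tags.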

Other observations

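Of the tests in this part, the scan of gene families, the thinning to 100 tags, the ratio of tags between short-tailed and long-tailed genes and the test on neuropeptide genes were chosen only after the result was seen. Gene families were scanned as 122 groups of at least 8 genes that share a symbol prefix; 21 lay in the lowest 2.5% of abundance-matched lists and 11 in the highest 2.5%, where chance would put 3.05 at each end. Among 81 families mostly outside the fixed lists 6 lay at each of these ends. The number by chance, 3.05, takes the genes of a family as independent, so it is only a rough guide, as for the lists. Short tails were found for the nssp genes (37 genes, median 63 nt against 84 nt in matched lists), the nspc nematode-specific peptide genes (12 genes, 62 nt, 12 of 12 below the median over genes), the spig genes (10 genes, 61 nt), the nspb genes (8 genes, 65.5 nt), the fungus-induced protein related fipr genes (11 genes, 61 nt) and the claudin-like clc genes (11 genes, 70 nt, percentile 2.32). Long tails were found for the carboxylesterase-domain cest genes (13 genes, 94 nt, percentile 98) and the gei genes (9 genes, 96 nt, percentile 98.5).

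The other families outside the lists in the highest 2.5% were unc, lin, let and dpy, named here because they lay there. The egl genes (egg-laying defective, 13 genes, of which 8 in fixed lists) had a median of 95 nt at percentile 99.4. The daf, ced, mig, sel and spe families, also named for mutant phenotypes, lay at percentiles 90.5, 92.7, 93.6, 91.6 and 91.7, and hpo at 5.65. The unc genes (uncoordinated movement) had a median of 88 nt, with 36 of 66 above the median over genes and 14 below, against 79 nt in matched lists, at percentile 100. The lin genes (cell lineage, 33 genes) had a median of 90.5 nt at percentile 99.7 and the let genes (lethal, 30 genes) of 84.5 nt at percentile 98.9. The dpy genes (dumpy body, 21 genes) had a median of 85 nt at percentile 99.4. The sma genes (small body) had a median of 110 nt, with 8 of 8 above. Some of these genes also belong to fixed lists, 16 of the unc, 10 of the lin, 5 of the let, 9 of the dpy and 4 of the sma genes. Within the F-box, MATH and BTB list the math genes (9 genes) had a median of 97 nt at percentile 97.7 and the bath genes (16 genes) of 79.5 nt at percentile 18; the difference between the families was not tested. Within the sperm list the major sperm protein msp genes had a median of 53 nt, with 23 of 23 below the median over genes, and the spe genes of 92 nt, with 6 of 9 above. Within the transcription factor list the nuclear receptor nhr genes had a median of 99 nt, with 59 of 73 above. The ztf genes had a median of 93 nt, with 9 of 15 above. The ceh genes had a median of 85 nt, against 84.5 nt in matched lists, with 5 of 15 above and 2 below. The ceh genes were therefore not long as a family.

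For the shorter tails of genes with more tags, 3 technical explanations were tested. Without ribosomal protein genes rho was -0.28, so the relation also held among the other genes. Ribosomal protein genes are 81 of the 8803 genes, and leaving them out could change a rank correlation only slightly. With each gene thinned to 100 tags rho was -0.29, so the relation also held at equal depth. Noise alone weakens a correlation rather than creating one, so this result says little about noisy medians as its source. Without tails at the end of the callable range rho was -0.29. In the group of genes with the fewest tags, such tails made up 0.91% of the tags of the median gene. Leaving them out could therefore move most medians only slightly, and this result says little about such tails as the source of the relation. A more efficient capture of short tails could raise the tag numbers of short-tailed genes and remains open, because no independent measure of abundance was analysed here; of 10 groups of genes by tail length, the shortest had 3.09 times the median tags of the longest, which only restates the relation. No biological explanation was tested, as the design has a single group.

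For the short tails of neuropeptide genes, one explanation tested was that one family of the list sets its median. Among the list's own genes 3 of 3 families lay under the 2.5th percentile of their matched lists, flp at 55 nt (28 genes), ins at 61 nt (14 genes) and nlp at 61 nt (37 genes), which argues against it. Neuropeptide, ribosomal protein, major sperm protein and histone genes encode small proteins, so a relation of tail length to transcript length, biological or through the size selection of fragments, may underlie several of these lists; it was not tested, because transcript lengths were not analysed here. No biological explanation was tested.

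Neighbouring analysed genes had slightly similar tails. Over 8773 pairs of analysed genes with no other analysed gene between them in the reference gene order, Spearman's rho of the medians, after the trend on tags was removed, was 0.065, above the range of -0.030 to 0.037 in 1000 shuffled orders, and it was 0.0088 for genes 10 apart. For the 3792 pairs with no annotated gene between them it was 0.092. Tags assigned to the gene next to their source may contribute, and so may shared regulation of clustered genes or operons; the value lay between the bounds set beforehand for assignment errors (0.1) and against them (0.05), so these cannot be told apart here.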
